A study of Mus musculus with 56 samples.

How the data were processed

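Total RNA of the medial geniculate nucleus was extracted with mirVana kits, and 100 ng were labelled with Cy3 per array, per the labels' protocols. The 56 arrays lay on 15 slides with places for 8 arrays each, scanned on 6 days, and came from 48 animals in 8 groups set by line, genotype and age. Slides 6, 10 and 11 held 1 genotype and the others both. No slide or scan day held both ages or both lines, so that age and line cannot be told apart from slide and scan day in the wild types.

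The deposited scanner files give intensity per spot, which is 1-colour Cy3 intensity per the labels. The authors extracted these intensities with Agilent Feature Extraction, version 10.5.1.1 per the submitters' processing notes and 10.7.3.1 per the file headers, and which of these is right stays open. The processed signal is background-subtracted and spatially detrended within an array but not normalized between arrays, per the file headers. The scanner software's summary per miRNA adds up its probes and stands at 0.1 where the miRNA was not detected. The authors' series values for the same 1247 miRNAs are on the log2 scale, by comparison with the scanner values (r from 0.978 to 0.992 per array, and from 0.911 to 0.965 for differences between arrays). Each column of them has the same distribution, with a median of 2.68, so that they appear quantile-normalized, but the method and any filter are not given in the sources used here.

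Each array held 49880 spots for 3105 probes beside 2164 control spots, which were left out, as were 2.99 to 4.73% of spots per array marked as outliers by the scanner software, and 0 spots were saturated. Spots of a probe were averaged. Each array was divided by the 75th percentile of its 504 probes (16.2%) detected on all arrays, where detected means that at least 50% of the spots were well above background. Probes of a miRNA were summed (1 to 4 probes, 4 miRNAs with 1). Levels under the floor of 9.06 (3.18 on the log2 scale) were set to it and log2 was taken, and both arrays of an animal were averaged. Of 1247 miRNAs the 470 detected in at least 4 animals were tested, and 289 of them were detected in all animals. The SD of the negative controls ran from 1.03 to 2.78 per array. A group with no animal well above background has only a bound: it is given as the brighter group's mean over the mean, per array, of the highest of the floor, the lowest signal well above background and the dim miRNA's own.

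A limma model with 1 mean per group was fitted to the 48 animals (residual degrees of freedom 40, prior 1.71, total 41.7), with two-sided moderated tests, empirical Bayes and Benjamini-Hochberg adjustment at 0.05. Contrasts were mutant minus wild type per line and age, the difference of these between ages and between lines, and 4 minus 2 months in wild types. The 4 mutant comparisons shared no animals, and the ages of wild types were compared with the same wild types as the mutants. Permutation tests were exact and two-sided for the miRNAs of the title, deleted-region and hippocampal lists, and drew 100000 resamples for brightness and spike-ins. Overlap was tested with Fisher's exact test, 1-sided. Lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, over 16 lists with at least 3 tested members. R 4.3.3, limma 3.58.1, data.table version 1.17.8, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used. Gene order is that of mouse assembly GRCm38.p6.

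The design, the alternatives, the 21 lists and the rule for naming miRNAs were fixed before the data were examined, except that scaling to the labelling spike-ins and array brightness as a covariate were added as alternatives afterwards. Per mutant comparison the rule names each tested miRNA of the lists of the title miRNA, the deleted region and the hippocampal pair (miR-25 and miR-185), up to 12 lower and 12 higher calls by size, the smallest p-values where fewer than 5 pass in a direction, the 3 members with the smallest p per list and up to 12 calls common to both lines at 1 age. For the differences between ages or lines and the wild-type ages it names up to 6 calls per direction, or the 3 with the smallest p. The lists were title miRNA, deleted region, hippocampal pair, DGCR8-independent, neuronal, oligodendrocyte, astrocyte, microglia and leukocyte, vascular, erythroid, choroid plexus and ependyma, neighbouring thalamic, hippocampal and cortical, sensory cluster, let-7, miR-17-92 and paralogs, miR-29, miR-30, Dlk1-Dio3, Sfmbt2, activity-regulated and viral probes, from general knowledge and not from these arrays. The viral list was empty, since all 1247 miRNAs are of mouse. Lists share members.

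The scripts were tested on 5 simulations of the 470 miRNAs, with 60 changed by each size. Differences of 0.25, 0.5 and 1 were recovered in 43.3, 82.7 and 99.3% for Df16 at 2 months and 38.7, 81.3 and 98.7% at 4 months. For Dgcr8 these were 54.3, 91 and 99%, and 54, 92 and 99%. With nothing changed 1 miRNA was called in Df16 at 4 months and 1 list in Dgcr8 at 4 months, and a moved list was called in 5 of 5 simulations. False calls made up 3.01, 3.10, 4.18 and 2.65% of calls in the same order. These rates need not hold for real arrays.

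Alternatives were other scalings (percentile over all probes, quantile, none, median), normexp with an offset of 50 on median spot and background signals, since the files hold no mean signal, the scanner's summary, other probe summaries, the authors' series values, other floors and filters, outlier spots kept, each comparison fitted alone, array weights, slide as a block (fixed, or random with a consensus correlation of 0.312), other thresholds, a replicate block and each animal left out in turn. Whether replicate numbers pair the animals was checked from deviations from group means: same-numbered Df16 animals correlated with r from 0.11 to 0.57 over 4 pairs at 2 months and from 0.37 to 0.49 over 4 pairs at 4 months, so the numbers were taken as pairs there.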

Results

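MicroRNA levels were measured in the medial geniculate nucleus, the auditory relay of the thalamus, of C57BL/6 mice of 2 mutant lines and their wild types. Df16 mice (Df(16)1/+) lack 1 copy of an interval of chromosome 16 that corresponds to the human 22q11 deletion, and Dgcr8 mice (Dgcr8+/-) lack 1 copy of Dgcr8, whose protein works with Drosha to cut primary microRNA transcripts. Dgcr8 lies within the Df16 interval. The Df16 groups held 4 mutants and 6 wild types at 2 months of age and 4 mutants and 4 wild types at 4 months. The Dgcr8 groups held 9 mutants and 7 wild types at 2 months and 7 mutants and 7 wild types at 4 months. The 48 animals gave 56 arrays, since the 8 Df16 animals at 4 months had 2 arrays each. Of the 1247 mouse miRNAs on the array, 470 were detected in at least 4 animals and tested. The number of arrays limits the precision of every value. Differences are mutant minus wild type on the log2 scale with the standard error (SE) of the limma fit, and adjusted p-values are limma's after Benjamini-Hochberg adjustment over the 470 miRNAs. Where leaving out 1 animal at a time (48 runs) ended a call in more than 2 runs, brackets give the number of these runs and, where each group had an animal well above background, the range of the difference over all runs.

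Array brightness before scaling was lower in mutants. The mean difference over the 4 comparisons was -0.23 on the log2 scale (permutation p = 1e-05, the smallest that 100000 resamples can give). Without scaling the median difference over all tested miRNAs was -0.29 for Df16 and -0.19 for Dgcr8 at 2 months, and -0.031 and -0.13 at 4 months. All other differences are relative to the bulk of detected miRNAs on each array, so a change common to all would not appear.

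The title of the series names miR-338-3p, an abundant miRNA of oligodendrocytes and neurons encoded within Aatk. In Df16 mutants miR-338-3p fell by 0.26 (SE 0.09) at 2 months and by 0.34 (SE 0.10) at 4 months, which was 16.6% and 21.2% below wild type (adjusted p = 0.0277 and 0.0116). In Dgcr8 mutants it fell by 0.30 (SE 0.07) at 4 months, 19.0% below wild type (adjusted p = 0.00116), and its difference of -0.10 (SE 0.07, adjusted p = 0.336) at 2 months did not pass the test. The number of mutants below the lowest wild type was 3 of 4 and 4 of 4 in Df16, and 1 of 9 and 6 of 7 in Dgcr8, at 2 and 4 months.

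Exact two-sided permutation tests of miR-338-3p gave p = 0.00952 and 0.0286 for Df16 and 0.223 and 0.00233 for Dgcr8 at 2 and 4 months. They ignored the Df16 pairs, without which 0.0286 is the smallest p for 4 against 4. The difference at 4 months minus that at 2 months was -0.082 (adjusted p = 0.916) in Df16 and -0.21 in Dgcr8 (95% interval -0.41 to -0.0041, adjusted p = 0.999), so that a change of the effect with age was not shown in either line. Within slides holding both genotypes miR-338-3p differed by -0.56 to -0.14 on 3 slides for Df16 at 2 months, by -0.19 to 0.14 on 4 slides for Dgcr8 at 2 months and by -0.38 to -0.26 on 3 slides for Dgcr8 at 4 months. With slide as a block the differences were -0.27 and -0.34 for Df16 and -0.092 and -0.32 for Dgcr8. All Df16 animals at 4 months lay on slides 1 and 2, so that the block cannot move their difference.

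With the percentile taken over all probes miR-338-3p passed in none of the comparisons (-0.24 and -0.36 in Df16, -0.27 in Dgcr8 at 4 months, adjusted p = 0.188, 0.154 and 0.0788). Both Df16 calls were lost with median scaling (-0.24 and -0.34, adjusted p = 0.0904 and 0.0674) and with scaling to the labelling spike-ins (-0.41 and -0.096, adjusted p = 0.0836 and 0.802). The call in Df16 at 2 months was also lost with the scanner software's summary per miRNA (-0.22), on the authors' series values (-0.19), with no filter and without mutant replicate 2 (-0.19), mutant replicate 4 (-0.25) or wild-type replicate 2 (-0.24). The call in Df16 at 4 months was also lost without scaling (-0.42), with normexp (-0.32), when its groups were fitted alone and without mutant replicate 2 (-0.30). In Dgcr8 at 2 months miR-338-3p passed with quantile normalization (-0.24, adjusted p = 0.00732) and without scaling (-0.36, adjusted p = 0.00527).

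The other arm, miR-338-5p, differed by -0.19 and -0.35 in Df16 and by -0.04 and -0.19 in Dgcr8 at 2 and 4 months, and passed in none of them (adjusted p = 0.416, 0.245, 0.890 and 0.363). With slide as a block it passed in Df16 at 4 months (adjusted p = 0.00229).

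**Figure D1:**
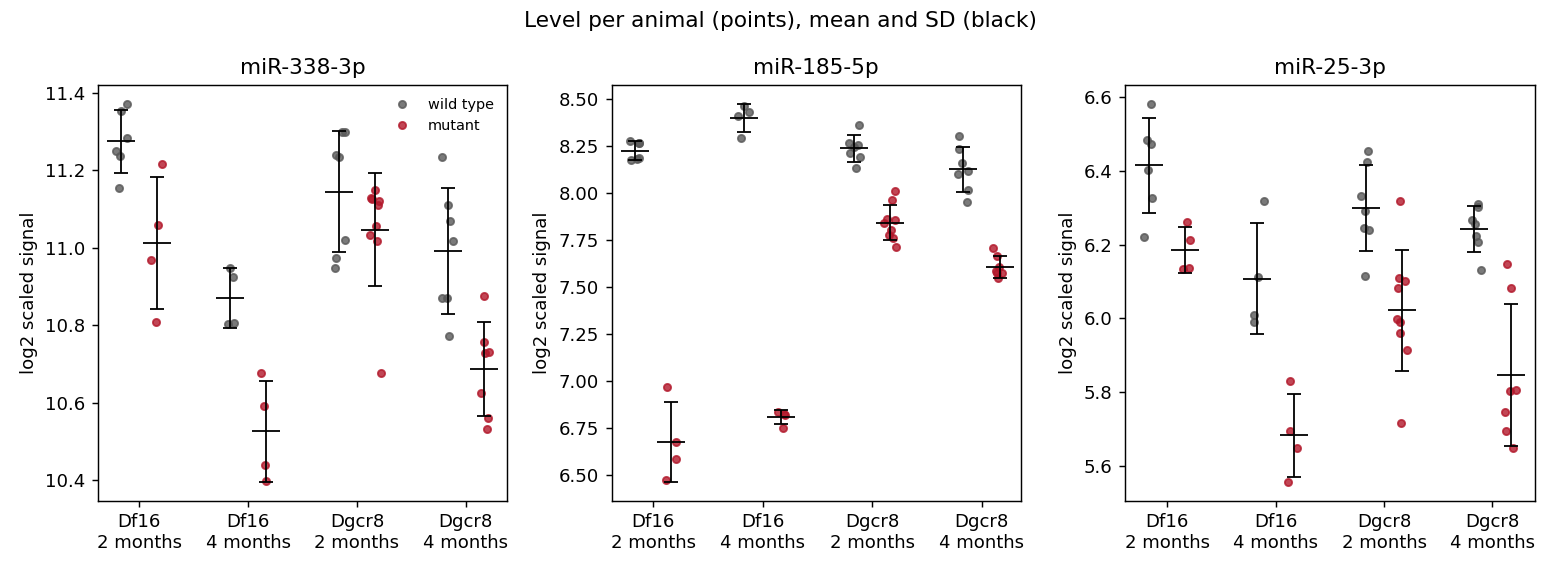
Level of miR-338-3p, miR-185-5p and miR-25-3p in each animal (log2 scaled signal, vertical axis) for wild types (grey) and mutants (red) per line and age (horizontal axis), with the group mean and SD in black. For miR-185-5p every mutant lies below every wild type of its own line and age.

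The gene of miR-185 lies inside Tango2, beside Dgcr8 in the deleted interval, and the gene of miR-1306 lies inside Dgcr8 itself. In Df16 mutants miR-185-5p fell by 1.55 (SE 0.06) at 2 months and by 1.59 (SE 0.07) at 4 months, to 34.2% and 33.1% of wild type (adjusted p = 1.44e-23 and 1.69e-22). In Dgcr8 mutants, which keep both copies of its gene, miR-185-5p fell by 0.40 (SE 0.05) and 0.52 (SE 0.05), to 76.0% and 69.8% (adjusted p = 4.06e-08 and 3.44e-10). Every mutant lay below the lowest wild type in each of the 4 comparisons, and miR-185-5p was lower in mutants on each slide that held both genotypes. The level of miR-1306-3p differed by 0.18 and -0.06 in Df16 and by 0.07 and 0.21 in Dgcr8, and passed in none of them (adjusted p = 0.683, 1, 0.866 and 0.486). It was well above background in 5 of 6 Df16 wild types, 6 of 9 Dgcr8 mutants and 5 of 7 Dgcr8 wild types at 2 months. Its sign turned with the scaling, so no direction is given for it.

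A further miRNA on the lists fixed in advance was miR-25-3p, of the miR-106b-25 cluster. It fell by 0.43 (SE 0.10) in Df16 at 4 months (adjusted p = 0.00172), and by 0.28 (SE 0.07) and 0.40 (SE 0.07) in Dgcr8 at 2 and 4 months (adjusted p = 0.00167 and 3.13e-05). In Df16 at 2 months miR-25-3p was at -0.23 (adjusted p = 0.0573), passed with slide as a block (-0.25, adjusted p = 0.0173) and was positive with normexp background correction (0.081).

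In Df16 mutants at 2 months 78 miRNAs were lower and 23 higher than in wild types. Beside miR-185-5p, those that fell furthest were mainly members of the imprinted Dlk1-Dio3 cluster on chromosome 12. There miR-379-3p fell by 0.88 (SE 0.13), miR-299b-5p by 0.88 (SE 0.13), miR-337-3p by 0.81 (SE 0.10), miR-544-5p by 0.70 (SE 0.14), miR-411-3p by 0.64 (SE 0.07), miR-411-5p by 0.63 (SE 0.09) and miR-376c-3p by 0.60 (SE 0.11). Outside it miR-153-3p, a neuronal miRNA, fell by 0.65 (SE 0.17), miR-340-3p by 0.64 (SE 0.13), miR-374c-5p by 0.60 (SE 0.16) and miR-325-3p by 0.60 (SE 0.09). Adjusted p-values of these falls ran from 2.26e-08 for miR-411-3p to 0.00479 for miR-374c-5p. With normexp background correction the differences of miR-379-3p, miR-299b-5p, miR-337-3p, miR-544-5p, miR-376c-3p, miR-340-3p, miR-374c-5p and miR-325-3p were positive, from 0.0060 for miR-337-3p to 0.23 for miR-544-5p. Well above background in only some animals were miR-379-3p, miR-299b-5p, miR-340-3p and miR-374c-5p (3 of 4 mutants each) and miR-544-5p (2 of 4 mutants). The difference of miR-340-3p was -0.36 without mutant replicate 1. The call of miR-153-3p ended without mutant replicate 1 (-0.44).

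Among the miRNAs that rose in Df16 at 2 months, miR-30d-5p, miR-30a-3p and miR-30a-5p of the miR-30 family were higher by 0.35 (SE 0.07), 0.33 (SE 0.07) and 0.30 (SE 0.07). Also higher were miR-320-3p, whose precursor is made without DGCR8, by 0.28 (SE 0.09), miR-344d-3p by 0.31 (SE 0.10) and miR-3096b-3p by 0.27 (SE 0.06). Without scaling these 6 differences were negative, from -0.13 for miR-3096b-3p to -0.046 for miR-30d-5p. The differences of miR-703 (0.92, adjusted p = 0.0298), miR-3095-3p (0.78, adjusted p = 0.00944), miR-5113 (0.77, adjusted p = 0.00936), miR-697 (0.39, adjusted p = 0.0444) and miR-677-3p (0.27, adjusted p = 0.0437) also passed. With the replicate block, which pairs animals of the same number, they did not, at 0.74, 0.70, 0.70, 0.40 and 0.26 (adjusted p = 0.0992, 0.0721, 0.0628, 0.116 and 0.0571). A further call, miR-3059-3p, was not well above background in any animal of either group, so that no size is given, and was lost with the replicate block (adjusted p = 0.0962). The split of the 101 calls was 64 lower and 48 higher with the percentile over all probes, 173 and 0 without scaling, 68 and 83 with median scaling, 16 and 243 with normexp, and 70 and 0 with spike-in scaling. The difference of miR-30d-5p was 0.22 without mutant replicate 1. The difference of miR-344d-3p was 0.48 without mutant replicate 2. With 1 animal left out, the calls of miR-344d-3p (4, 0.22 to 0.48), miR-703 (6, 0.67 to 1.18), miR-697 (6, 0.34 to 0.51), miR-677-3p (3, 0.076 to 0.37) and miR-3059-3p (4) ended. The calls of miR-320-3p (0.13), miR-3095-3p (0.65), miR-5113 (0.62) and miR-677-3p (0.076) ended without mutant replicate 1. The call of miR-320-3p ended also without wild-type replicate 3 (0.24). Fewer than 2 in 3 alternatives kept the calls of miR-344d-3p (13 of 21), miR-703 (11 of 21), miR-697 (12 of 21), miR-677-3p (11 of 22) and miR-3059-3p (9 of 21). Only some animals were well above background for miR-344d-3p (2 of 4 mutants and 4 of 6 wild types), miR-703 (2 of 6 wild types) and miR-697 (2 of 4 mutants).

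In Df16 mutants at 4 months 41 miRNAs were lower and 9 higher. After miR-185-5p the furthest falls were those of miR-674-5p, by 0.95 (SE 0.11), and miR-532-3p, by 0.57 (SE 0.11), and of Dlk1-Dio3 members. Of the latter miR-337-5p fell by 0.62 (SE 0.11), miR-411-5p by 0.54 (SE 0.10), miR-379-5p by 0.52 (SE 0.11), miR-337-3p by 0.52 (SE 0.11) and miR-376c-3p by 0.48 (SE 0.12). From the same cluster miR-134-5p, which acts in dendrites, was at least 1.43-fold lower (adjusted p = 0.0146), being not well above background in any mutant. Further falls were those of miR-874-3p, by 0.49 (SE 0.10), miR-340-5p, by 0.48 (SE 0.06), and the neuronal miR-218-5p, by 0.37 (SE 0.09). With normexp the difference of miR-532-3p was 0.0028. Adjusted p-values of these falls lay between 1.70e-08 for miR-674-5p and 0.0146 for miR-134-5p. Of 4 mutants 1 was well above background for miR-674-5p. The call of miR-134-5p ended without mutant replicate 1 (adjusted p = 0.0759) or wild-type replicate 4 (adjusted p = 0.0864).

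The 9 miRNAs that rose in Df16 at 4 months were miR-1298-3p, by 1.02 (SE 0.27), miR-135a-2-3p, by 0.80 (SE 0.20), miR-7b-5p, by 0.69 (SE 0.23) and miR-3102-3p, by 0.35 (SE 0.08). The others were miR-1839-5p and miR-1839-3p, by 0.32 (SE 0.07) and 0.22 (SE 0.07), miR-301a-3p, by 0.23 (SE 0.08), miR-3096b-3p, by 0.22 (SE 0.07), and miR-125b-5p, by 0.21 (SE 0.06). Both miR-130b-3p and miR-212-5p passed while not well above background in any animal of either group, so no size is given for them. The split of the 50 calls was 14 lower and 0 higher without scaling, 3 and 0 with normexp and 1 and 6 with spike-in scaling. Leaving out 1 animal ended the calls of miR-7b-5p (34, 0.51 to 0.90), miR-1839-3p (3, 0.18 to 0.29), miR-301a-3p (36, 0.19 to 0.31), miR-3096b-3p (4, 0.18 to 0.26), miR-125b-5p (3, 0.16 to 0.26) and miR-212-5p (7). The call of miR-1298-3p ended without mutant replicate 3 (0.55). The call of miR-135a-2-3p ended without wild-type replicate 3 (0.53). Of these calls miR-7b-5p (11 of 24), miR-301a-3p (9 of 24), miR-125b-5p (15 of 24) and miR-212-5p (11 of 23) were kept in fewer than 2 in 3 alternatives. Background was not well exceeded in every animal for miR-1298-3p (1 of 4 wild types), miR-135a-2-3p (3 of 4 wild types) and miR-3102-3p (2 of 4 wild types).

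In Dgcr8 mutants at 2 months 80 miRNAs were lower and 31 higher. Of Dlk1-Dio3 members miR-379-3p fell by 0.74 (SE 0.10), miR-544-5p by 0.67 (SE 0.11), miR-337-3p by 0.63 (SE 0.08) and miR-299b-5p by 0.62 (SE 0.10). Further members that fell were miR-411-3p by 0.61 (SE 0.06), miR-411-5p by 0.60 (SE 0.07), miR-539-5p by 0.60 (SE 0.10), miR-379-5p by 0.59 (SE 0.08) and miR-376c-3p by 0.56 (SE 0.08). Outside the cluster miR-374c-5p fell by 0.65 (SE 0.13) and miR-582-3p by 0.59 (SE 0.08). Both arms of miR-342, a miRNA of leukocytes and microglia, fell, miR-342-5p by 0.41 (SE 0.07) and miR-342-3p by 0.27 (SE 0.07), and the neuronal miR-488-3p fell by 0.47 (SE 0.09). Adjusted p-values of these falls ran from 5.89e-11 for miR-411-3p to 0.00250 for miR-342-3p. With normexp 9 calls were left, and the differences of miR-379-3p, miR-540-5p, miR-544-5p, miR-299b-5p, miR-539-5p, miR-376c-3p, miR-374c-5p, miR-582-3p, miR-342-5p and miR-488-3p were positive, from 0.021 for miR-376c-3p to 0.16 for miR-539-5p. Levels of miR-540-5p (2 of 9 mutants), miR-544-5p and miR-374c-5p (8 of 9 mutants each), miR-539-5p (4 of 9 mutants) and miR-582-3p (3 of 9 mutants and 6 of 7 wild types) were well above background in only some animals. The fall of miR-540-5p passed (adjusted p = 2.65e-10), but most mutants lay at or near the floor, which sets its size, so that none is given. For miR-582-3p and miR-539-5p the floor sets the size in part.

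Of the 31 miRNAs higher in Dgcr8 at 2 months, miR-34a-5p, which p53 induces, rose by 0.44 (SE 0.12), miR-1892 by 0.46 (SE 0.17), miR-296-5p by 0.35 (SE 0.10) and miR-344d-3p by 0.32 (SE 0.08). Smaller were those of miR-1895 by 0.31 (SE 0.10), miR-3102-3p by 0.30 (SE 0.06), miR-5126 by 0.29 (SE 0.09), miR-92a-3p by 0.28 (SE 0.08), miR-1839-5p by 0.26 (SE 0.05) and miR-1839-3p by 0.25 (SE 0.05). Both arms of miR-1839 were slightly negative without scaling (-0.0038 and -0.012). The differences of miR-5113 (0.49, adjusted p = 0.0385) and miR-3095-3p (0.48, adjusted p = 0.0404) passed, and did not with slide as a block (0.40, adjusted p = 0.139, and 0.39, adjusted p = 0.142). The split of the 111 calls was 60 lower and 43 higher with the percentile over all probes, 141 and 0 without scaling and 74 and 0 with spike-in scaling. In single runs, the calls of miR-1892 (9, 0.35 to 0.56), miR-5113 (9, 0.38 to 0.62) and miR-3095-3p (9, 0.39 to 0.63) ended. The call of miR-1895 ended without wild-type replicate 5 (0.25). The calls kept in fewer than 2 in 3 alternatives were miR-1892 and miR-5113 (10 of 22 each) and miR-3095-3p (9 of 22). In some animals miR-344d-3p (8 of 9 mutants and 6 of 7 wild types) lay near background.

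In Dgcr8 mutants at 4 months 84 miRNAs were lower and 6 higher. Of Dlk1-Dio3 members miR-299b-5p fell by 0.79 (SE 0.11), miR-379-3p by 0.75 (SE 0.10), miR-337-3p by 0.64 (SE 0.08), miR-337-5p by 0.64 (SE 0.08) and miR-379-5p by 0.64 (SE 0.08). Next were miR-411-3p by 0.61 (SE 0.06), miR-411-5p by 0.59 (SE 0.08), miR-409-3p by 0.59 (SE 0.08) and miR-323-3p by 0.55 (SE 0.09). In the same cluster miR-540-5p was at least 1.42-fold lower (adjusted p = 2.04e-07), being not well above background in any mutant. Outside it miR-374c-5p fell by 0.74 (SE 0.14) (5 of 7 mutants well above background) and miR-325-3p by 0.65 (SE 0.08). The neuronal miR-212-5p, of the activity-regulated miR-132 and miR-212 cluster, fell by 0.48 (SE 0.08), miR-488-3p by 0.43 (SE 0.09) and miR-218-5p by 0.31 (SE 0.07), and miR-342-3p and miR-342-5p fell by 0.33 (SE 0.07) and 0.33 (SE 0.08). Adjusted p-values of these falls ran from 3.42e-10 for miR-411-3p to 9.75e-04 for miR-342-5p. With normexp 13 calls were left, and miR-379-3p (0.011), miR-374c-5p (0.012), miR-325-3p (0.047), miR-540-5p (0.10), miR-342-5p (0.10), miR-212-5p (0.057) and miR-488-3p (0.0089) had positive differences.

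The 6 miRNAs that rose in Dgcr8 at 4 months were miR-1843a-5p, by 0.20 (SE 0.06), miR-3102-3p, by 0.19 (SE 0.06), miR-3096b-3p, by 0.17 (SE 0.05), miR-1839-5p, by 0.17 (SE 0.05), miR-484, whose maturation does not need DGCR8, by 0.16 (SE 0.05), and miR-1839-3p, by 0.15 (SE 0.05). With spike-in scaling all 6 had negative differences, from -0.13 for miR-1839-3p to -0.083 for miR-1843a-5p. Without scaling miR-484 (-0.0030) and miR-1839-3p (-0.020) were negative, and miR-1839-3p did not pass with slide as a block (adjusted p = 0.0694). The split of the 90 calls was 59 lower and 13 higher with the percentile over all probes and 107 and 70 with slide as a block. With 1 animal left out, the calls of miR-1843a-5p (3, 0.15 to 0.22) and miR-1839-3p (4, 0.12 to 0.17) ended. Alternatives kept miR-1839-3p (12 of 22) in fewer than 2 in 3 cases.

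The Dlk1-Dio3 list had 55 tested members of 93 on the array. Of these, 25 were lower and 1 higher in Df16 at 2 months, 11 lower in Df16 at 4 months, 25 lower in Dgcr8 at 2 months and 23 lower in Dgcr8 at 4 months. Of the 415 other miRNAs 53, 30, 55 and 61 were lower. Adjusted over the list alone, 27 were lower and 1 higher, 12 lower, 30 lower and 2 higher, and 28 lower. The median difference of the members was -0.25, -0.09, -0.23 and -0.19 in the same order, but with normexp it was 0.095, 0.011 and 0.021 in the first 3, and with spike-in scaling it was 0.11 in Df16 at 4 months.

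By camera with its preset correlation the Dlk1-Dio3 list ranked lower than the other miRNAs in each comparison (adjusted p = 7.05e-10, 0.0172, 2.51e-10 and 1.07e-07), and none of these calls held with an estimated correlation (adjusted p = 0.973, 0.75, 0.881 and 0.996). Under normexp the median and the test differed in sign, since camera still ranked the list lower in Df16 at 2 months (adjusted p = 0.00103) and Dgcr8 at 2 months (adjusted p = 8.11e-10). By fry, which tests whether the members move one way on balance, adjusted p was 0.00702, 0.293, 0.00144 and 0.00241. Within slides the Dlk1-Dio3 median lay between -0.42 and -0.17 on 3 slides for Df16 at 2 months, between -0.31 and -0.19 on 4 slides for Dgcr8 at 2 months and between -0.35 and -0.16 on 3 slides for Dgcr8 at 4 months. With slide in the model it was -0.20, -0.094, -0.26 and -0.18. The camera call of Dlk1-Dio3 in Df16 at 4 months was lost with normexp, on the authors' series values, over miRNAs detected in all animals, with array weights and with spike-in scaling. It was also lost without mutant replicate 3 (median -0.043) or wild-type replicate 1 (median -0.019).

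Choroid plexus and ependymal miRNAs, which mark the lining of the ventricles, had 6 tested members of 23 and stood higher in Df16 mutants at 4 months, with a median difference of 0.78 (camera adjusted p = 0.0172, and adjusted p = 0.75 with an estimated correlation). By limma 0 of the 6 passed over all miRNAs, with 3 at an unadjusted p under 0.05, and 3 passed when adjusted over the list alone. The choroid plexus miRNA miR-204-5p differed by 0.77 (SE 0.27, adjusted p = 0.0604) and did not pass, nor did miR-211-5p (adjusted p = 0.0549), well above background in 1 mutant only. The latter passed with slide as a block (adjusted p = 0.0238) and with the replicate block (adjusted p = 0.00555). The list's value rested on mutant replicate 3, without which the median was 0.0082. The camera call was also lost without wild-type replicate 1 (median 0.77), with slide as a block, over miRNAs detected in all animals, when the groups were fitted alone, with array weights (median 0.058) and with spike-in scaling. In Df16 at 2 months and in Dgcr8 at 2 and 4 months the median of the list was -0.05, 0.05 and -0.08, with 0 members passing by limma and 0, 0 and 0 at an unadjusted p under 0.05.

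Of 7 tested on the DGCR8-independent list, miR-484 and miR-320-3p rose at 2 months, by 0.22 (SE 0.06) and 0.28 (SE 0.09) in Df16. In Dgcr8 they rose by 0.24 (SE 0.05) and 0.24 (SE 0.07). The list may be incomplete. At 4 months miR-484 alone passed in Dgcr8, and by limma 0 of the 7 in Df16 (0 at an unadjusted p under 0.05). The median was 0.22 and 0.04 in Df16 and 0.14 and 0.09 in Dgcr8 at 2 and 4 months, camera called none of these, and fry gave adjusted p = 0.0239 for Dgcr8 at 2 months. Without scaling miR-484 and miR-320-3p were negative at 2 months (-0.18 and -0.12 in Df16, -0.024 and -0.025 in Dgcr8). The call of miR-320-3p in Df16 at 2 months ended without mutant replicate 1 (0.13) or wild-type replicate 3 (0.24).

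Of the 26 tested neuronal miRNAs limma called 4 lower and 3 higher in Df16 at 2 months and 2 and 2 at 4 months. In Dgcr8 it called 3 and 3 at 2 months and 3 and 0 at 4 months. Among them miR-125b-5p rose by 0.17 (SE 0.06) and 0.18 (SE 0.04) in Df16 and Dgcr8 at 2 months but was negative without scaling (-0.23 and -0.083) and, in Df16, with quantile normalization (-0.022). A further member, miR-212-5p, fell by 0.52 (SE 0.10) in Df16 at 2 months. Of 4 oligodendrocyte miRNAs, which include both arms of miR-338, miR-338-3p alone passed in Df16 at each age and in Dgcr8 at 4 months, and miR-219-2-3p rose by 0.23 (SE 0.08) in Dgcr8 at 2 months. Of 7 microglial and leukocyte miRNAs limma called 0 in Df16 at 2 months (2 at an unadjusted p under 0.05). At 4 months miR-342-5p fell by 0.35 (SE 0.10) in Df16 (3 of 4 mutants well above background) but was at 0.020 with normexp. Both arms of miR-342 were the 2 lower ones in Dgcr8 at each age (fry adjusted p = 0.0365 at 4 months). Of 8 vascular miRNAs limma called 0 in each of the 4 comparisons (0, 0, 0 and 0 at an unadjusted p under 0.05). Of 15 astrocyte miRNAs miR-26a-5p rose by 0.16 (SE 0.04) in Df16 and miR-29a-3p by 0.19 (SE 0.05) in Dgcr8 at 2 months, and limma called 0 at 4 months (1 and 3 at an unadjusted p under 0.05). Of 6 erythroid miRNAs miR-15b-5p fell by 0.32 (SE 0.11) in Df16 at 2 months and by 0.29 (SE 0.09) in Dgcr8 at 4 months, 1 was higher in Dgcr8 at 2 months, and limma called 0 in Df16 at 4 months (2 at an unadjusted p under 0.05). With the percentile over all probes miR-26a-5p, miR-15b-5p, miR-219-2-3p and miR-29a-3p did not pass (adjusted p from 0.0588 for miR-29a-3p to 0.190 for miR-15b-5p in Dgcr8), and without scaling miR-26a-5p (-0.24), miR-219-2-3p (-0.033) and miR-29a-3p (-0.072) were negative. With slide as a block miR-219-2-3p did not pass (adjusted p = 0.0951). Leaving out 1 animal ended the calls of miR-125b-5p (4, 0.14 to 0.19) and miR-15b-5p (4, -0.38 to -0.15) in Df16 at 2 months. The calls of miR-15b-5p (-0.15) and miR-26a-5p (0.11) ended without mutant replicate 1 in Df16 at 2 months. In single runs, the call of miR-342-5p (4, -0.47 to -0.26) ended in Df16 at 4 months. With 1 animal left out, the call of miR-219-2-3p (5, 0.21 to 0.29) ended in Dgcr8 at 2 months. The call of miR-15b-5p in Dgcr8 at 4 months ended without mutant replicate 2 (-0.25) or mutant replicate 7 (-0.25). Fewer than 2 in 3 alternatives kept miR-125b-5p and miR-15b-5p (13 of 22 each) in Df16 at 2 months, miR-342-5p (10 of 23) in Df16 at 4 months and miR-219-2-3p (9 of 22) in Dgcr8 at 2 months.

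In the let-7 family of 14 tested members miR-98-5p fell by 0.39 (SE 0.08) in Df16 at 2 months and by 0.18 (SE 0.06) and 0.28 (SE 0.07) in Dgcr8 at 2 and 4 months, and limma called 0 in Df16 at 4 months (1 at an unadjusted p under 0.05). In Dgcr8 at 2 months 3 members rose, among them let-7b-5p by 0.20 (SE 0.06) and let-7c-5p by 0.20 (SE 0.07), which without scaling were at -0.067 and -0.064. With slide as a block miR-98-5p (adjusted p = 0.0951), let-7b-5p (adjusted p = 0.0937) and let-7c-5p (adjusted p = 0.126) did not pass in Dgcr8 at 2 months. Of 9 tested miR-30 family members 1 was lower and 3 were higher in each line at 2 months, where miR-30c-2-3p rose by 0.25 (SE 0.07) in Dgcr8 but was at -0.018 without scaling. The member miR-30e-5p fell by 0.18 (SE 0.05) in Df16 at 4 months and by 0.16 (SE 0.04) and 0.21 (SE 0.04) in Dgcr8 at 2 and 4 months, and miR-30e-3p by 0.18 (SE 0.04) in Dgcr8 at 4 months. With spike-in scaling miR-30e-5p was at 0.063 in Df16 at 4 months. Both miR-30a-3p and miR-30a-5p rose in Dgcr8 at 2 months, by 0.20 (SE 0.06) and 0.20 (SE 0.06), but were at -0.069 and -0.067 without scaling, and miR-30a-3p did not pass with slide as a block (adjusted p = 0.0509). The difference of miR-98-5p was -0.26 without mutant replicate 1 in Df16 at 2 months. The call of miR-30e-5p in Df16 at 4 months ended without mutant replicate 2 (-0.16). Leaving out 1 animal ended the call of miR-98-5p (9, -0.20 to -0.17) in Dgcr8 at 2 months. The calls of let-7b-5p (0.17) and let-7c-5p (0.18) ended without wild-type replicate 5 in Dgcr8 at 2 months. Under 2 in 3 alternatives kept let-7b-5p and let-7c-5p (13 of 22 each), miR-98-5p (11 of 22) and miR-30a-5p (14 of 22) in Dgcr8 at 2 months.

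Of 11 members of the miR-17-92 cluster and its paralogs miR-25-3p was the 1 lower in Df16 at 4 months and in Dgcr8 at each age. In Dgcr8 at 2 months miR-92a-3p was the 1 higher, and limma called 0 in Df16 at 2 months (3 at an unadjusted p under 0.05). Of 6 miR-29 family members miR-29a-3p alone passed, in Dgcr8 at 2 months, and limma called 0 in the other comparisons (0, 0 and 1 at an unadjusted p under 0.05 in Df16 at 2 and 4 months and Dgcr8 at 4 months). Of 14 Sfmbt2 cluster members (chromosome 2) miR-467e-5p was lower in Df16 and Dgcr8 at 2 months (adjusted p = 0.0440 and 0.00535). It was well above background in 0 mutants and in 2 of 6 and 3 of 7 wild types, so no size is given. It had a positive difference under normexp (0.28 and 0.17) and, in Df16, under median scaling (0.11). The call of miR-467e-5p was lost with the replicate block in Df16 (adjusted p = 0.105) and with slide as a block in Dgcr8 (adjusted p = 0.0765). In that cluster miR-467b-5p fell by 0.39 (SE 0.13) in Dgcr8 at 2 months (8 of 9 mutants well above background, adjusted p = 0.0616 with slide as a block, 0.11 under normexp). At 4 months miR-466b-3p (well above background in 2 of 7 wild types only) was lower in Dgcr8 (adjusted p = 0.0222), and limma called 0 in Df16 (0 at an unadjusted p under 0.05). With 1 animal left out, the calls of miR-467e-5p (8) in Df16 and miR-467b-5p (3, -0.50 to -0.31) in Dgcr8 at 2 months ended. The call of miR-466b-3p in Dgcr8 at 4 months ended without wild-type replicate 2 (adjusted p = 0.0629) or wild-type replicate 3 (adjusted p = 0.0523). The calls of miR-467e-5p (12 of 21) in Df16 and miR-467e-5p and miR-467b-5p (12 of 21 each) in Dgcr8 at 2 months, and miR-466b-3p (11 of 21) at 4 months, were kept in fewer than 2 in 3 alternatives.

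Of 13 miRNAs of neighbouring thalamic, hippocampal and cortical tissue, miR-382-3p, miR-382-5p and miR-7a-1-3p fell in Df16 at 2 months, by 0.57 (SE 0.11), 0.26 (SE 0.09) and 0.39 (SE 0.09), and in Dgcr8 at 4 months, by 0.41 (SE 0.09), 0.36 (SE 0.07) and 0.26 (SE 0.08). In Dgcr8 at 2 months miR-382-3p and miR-382-5p fell by 0.27 (SE 0.08) and 0.24 (SE 0.07), while miR-219-2-3p was higher, and in Df16 at 4 months miR-7b-5p was higher. With normexp miR-382-3p (0.0046 and 0.0070 at 2 months) and miR-7a-1-3p (0.13 in Df16 at 2 months, 0.020 in Dgcr8 at 4 months) had positive differences. Of 8 activity-regulated miRNAs miR-212-5p was lower in Df16 at each age and in Dgcr8 at 4 months, miR-134-5p in Df16 at 4 months, and miR-219-2-3p was higher in Dgcr8 at 2 months. Camera called no list but Dlk1-Dio3 and choroid plexus in the 4 comparisons, and 0 of the 6 members of the sensory cluster were tested. Adjusted over the list alone the counts differed only for miR-30 (2 lower and 4 higher in Df16 and 1 and 4 in Dgcr8 at 2 months), Sfmbt2 (0 in Df16 at 2 months and Dgcr8 at 4 months) and miR-25-3p with miR-185-5p (2 lower in Df16 at 2 months). In Df16 at 4 months they differed for both arms of miR-338 (2 lower), neuronal (3 lower and 3 higher), neighbouring tissue (2 higher) and miR-17-92 (2 lower), beside the lists above. The call of miR-382-5p in Df16 at 2 months ended without mutant replicate 2 (-0.17) or mutant replicate 4 (-0.23). The call of miR-7a-1-3p in Df16 at 2 months ended without mutant replicate 1 (-0.25).

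Many miRNAs were lower in both lines. At 2 months 65 were, of 78 in Df16 and 80 in Dgcr8, against 13.3 for independent lists (Fisher's exact p = 1.58e-51), and at 4 months 40 were, of 41 and 84, against 7.33 for independent lists (Fisher's exact p = 3.32e-33). Those higher in both were 13 at 2 months (1.52 for independent lists, Fisher's exact p = 2.18e-11) and 4 at 4 months (0.115 for independent lists, Fisher's exact p = 9.25e-07). In all 4 comparisons 30 miRNAs were lower, among them miR-185-5p, both arms of miR-411, miR-337, miR-490, miR-532 and miR-674, and miR-379-5p, miR-376c-3p, miR-340-5p and miR-873a-5p. At 2 months miR-369-3p of the Dlk1-Dio3 cluster fell by 0.57 (SE 0.14) in Df16 (3 of 4 mutants well above background) and by 0.52 (SE 0.11) in Dgcr8, but was at 0.32 and 0.047 with normexp. The 4 higher in all 4 comparisons were miR-1839-5p, miR-1839-3p, miR-3096b-3p and miR-3102-3p, all negative in Df16 at 2 months without scaling (-0.19 to -0.13). Fisher's test treats miRNAs as independent, which members of 1 cluster are not. With normexp 5 and 3 miRNAs were lower in both lines at 2 and 4 months. The call of miR-1839-5p in Df16 at 2 months ended without mutant replicate 3 (0.16). Leaving out 1 animal ended the call of miR-873a-5p (4, -0.56 to -0.40) in Df16 at 4 months. The call of miR-490-3p in Df16 at 4 months ended without mutant replicate 1 (-0.42) or wild-type replicate 2 (-0.39).

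Across the 470 miRNAs the differences of both lines correlated with Pearson's r of 0.79 (Spearman's rho 0.75) at 2 months and 0.66 (rho 0.69) at 4 months. Between the ages r was 0.52 (rho 0.50) in Df16 and 0.85 (rho 0.76) in Dgcr8. These are correlations across miRNAs, which are not independent replicates.

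**Figure D2:**
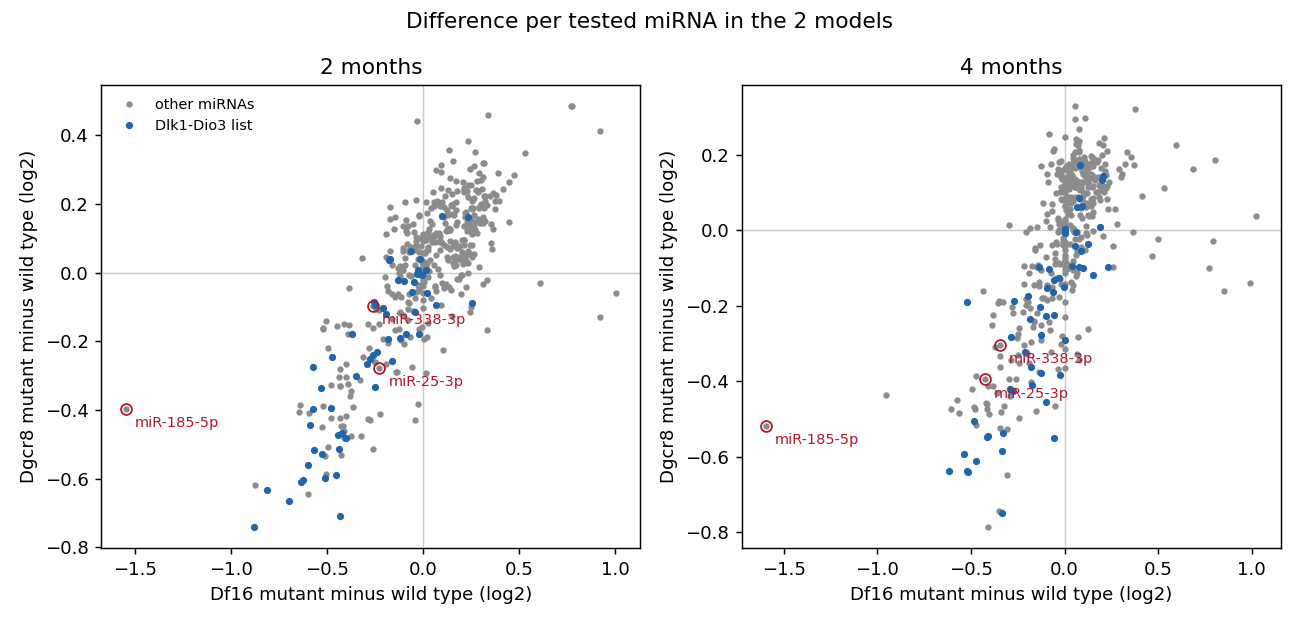
Log2 difference of mutant minus wild type for each of the 470 tested miRNAs in Df16 (horizontal axis) and Dgcr8 (vertical axis) at 2 and 4 months, with members of the Dlk1-Dio3 list in blue, other miRNAs in grey and 3 miRNAs circled. At both ages miR-185-5p lies far to the left of the other points.

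At each age miR-185-5p alone differed between the lines in its mutant effect, by -1.15 (SE 0.08, adjusted p = 5.81e-15) at 2 months and -1.08 (SE 0.09, adjusted p = 9.18e-13) at 4 months, with 18 and 17 miRNAs at an unadjusted p under 0.05. The count at 4 months was 148 with spike-in scaling and 67 with array weights. It was 4 without Df16 wild-type replicate 1, 3 without Df16 mutant replicate 1 or 3 or Dgcr8 wild-type replicate 3 and 2 without Df16 wild-type replicate 1 at 2 months, Dgcr8 mutant replicate 5 at 2 months or Dgcr8 wild-type replicate 5. For the change of the mutant effect with age limma called 0 miRNAs in Df16 and 0 in Dgcr8, with 38 and 19 at an unadjusted p under 0.05. The smallest p-values were those of miR-505-5p, miR-582-5p and miR-674-5p (-0.52, 1 of 4 mutants well above background at 4 months) in Df16 (adjusted p = 0.184 each), and of miR-151-5p (-0.31), miR-350-3p (-0.25) and miR-325-5p in Dgcr8 (adjusted p = 0.899 each). Those without a size were not well above background in any animal of 3 of the 4 groups. With slide as a block miR-674-5p passed (-0.58, adjusted p = 0.0339), and 1 miRNA was called in Df16 without mutant replicate 3 or wild-type replicate 1 at 4 months and in Dgcr8 without mutant replicate 2 at 4 months. A miRNA called at 1 age or in 1 line is therefore not shown to differ between them.

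By camera, the lists that shifted with age in the mutant effect were choroid plexus (0.78), miR-30 (-0.13) and Dlk1-Dio3 (0.12) in Df16 (adjusted p = 0.0242, 0.00500 and 1.21e-06). In Dgcr8 they were oligodendrocyte (-0.18), erythroid (-0.24), let-7 (-0.14) and miR-30 (-0.11) (adjusted p = 0.0432, 0.00213, 0.0147 and 0.0191). Between the lines oligodendrocyte (-0.17), erythroid (-0.18) and let-7 (-0.14) miRNAs differed at 2 months (adjusted p = 0.0427, 0.0427 and 0.00598). At 4 months choroid plexus (0.85) and Dlk1-Dio3 (0.12) miRNAs differed (adjusted p = 0.00305 and 1.84e-04). With an estimated correlation none of these passed, the lowest adjusted p being 0.422.

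Wild types of 4 and 2 months were compared within each line, but the ages lay on different slides and scan days, so that age and batch cannot be told apart. In the Df16 line 161 miRNAs were lower and 138 higher at 4 months, and in the Dgcr8 line 31 were lower and 119 higher. In the Df16 line miR-9-5p, a neural miRNA, fell by 1.97 (SE 0.07), miR-135a-5p decreased by 3.05 (SE 0.20) and miR-126-5p, an endothelial miRNA, by 2.03 (SE 0.23) (2 of 4 well above background at 4 months), while miR-5121 rose by 3.89 (SE 0.27). There miR-1249-3p, not well above background in any animal at 2 months, was at least 21.1-fold higher (adjusted p = 9.25e-35). In the Dgcr8 line miR-409-5p fell by 0.48 (SE 0.09) and miR-212-3p by 0.41 (SE 0.13), while miR-6243 rose by 1.48 (SE 0.14), miR-5099 by 1.45 (SE 0.12) and miR-188-5p by 1.41 (SE 0.17). By camera neuronal (-0.10, adjusted p = 0.0241) and Dlk1-Dio3 (-0.14, adjusted p = 9.54e-06) miRNAs were lower in the Dgcr8 line, with adjusted p = 0.988 each with an estimated correlation. The Dgcr8 split ran from 200 lower and 81 higher with the percentile over all probes to 3 and 109 with spike-in scaling. The Df16 split was 58 and 158 with normexp and 237 and 66 with spike-in scaling.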

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

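The tests of slide for the brightness of arrays, of gene copy number for miR-185-5p and of array scaling for miR-185-5p were chosen after their results were seen, and the other tests here before.

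In 32 of 408 groups of animals (7.84%, over the 111 miRNAs named with a group comparison) 1 animal stood apart from the others of its group by Dixon's test of the gap over the range, and in 24 of 388 (6.19%) without the groups in which an animal lay at the floor, where any value above it can stand apart. Chance gives about 1 in 20. Levels are on the log2 scale, with 3.18 as the floor. Df16 mutant replicate 1 at 2 months had miR-379-3p at 3.74 (others 4.56 to 4.68), miR-30d-5p at 9.84 (others 9.28 to 9.35), miR-677-3p at 6.57 (others 5.70 to 5.84), miR-98-5p at 6.80 (others 7.27 to 7.36) and miR-15b-5p at 6.39 (others 7.02 to 7.08). Df16 mutant replicate 1 at 4 months had miR-338-5p at 4.58 (others 4.84 to 4.89). Df16 mutant replicate 3 at 4 months had miR-337-5p at 4.68 (others 4.89 to 4.92), miR-1839-5p at 7.36 (others 7.50 to 7.51), miR-204-5p at 12.05 (others 9.23 to 9.43) and miR-211-5p at 6.00 (others 4.77 to 4.91). Df16 wild-type replicate 3 at 4 months had miR-379-5p at 7.41 (others 7.69 to 7.71), miR-873a-5p at 6.24 (others 6.60 to 6.63) and miR-126-5p at 5.20 (others 4.08 to 4.27). Df16 wild-type replicate 1 at 4 months had miR-376c-3p at 5.97 (others 5.41 to 5.50) and miR-505-5p at 3.24 (others 3.18). Dgcr8 mutant replicate 5 at 2 months had miR-338-3p at 10.68 (others 11.02 to 11.15), miR-540-5p at 3.61 (others 3.18 to 3.27), miR-34a-5p at 9.30 (others 9.85 to 10.29), miR-151-5p at 8.55 (others 8.83 to 9.08), miR-350-3p at 7.14 (others 7.34 to 7.39) and miR-219-2-3p at 8.25 (others 8.56 to 8.88). Dgcr8 mutant replicate 2 at 2 months had miR-544-5p at 3.18 (others 3.89 to 4.54), miR-5126 at 9.58 (others 8.82 to 9.17) and miR-3096b-3p at 6.21 (others 5.76 to 5.98). Dgcr8 mutant replicate 2 at 4 months had miR-299b-5p at 3.97 (others 4.18 to 4.30). Dgcr8 mutant replicate 4 at 2 months had miR-325-5p at 3.19 (others 3.18). Dgcr8 wild-type replicate 4 at 4 months had miR-325-5p at 3.46 (others 3.18 to 3.30). Df16 wild-type replicate 6 at 2 months had miR-1249-3p at 3.33 (others 3.18). Df16 wild-type replicate 2 at 4 months had miR-1249-3p at 7.49 (others 7.75 to 7.76). Df16 wild-type replicate 5 at 2 months had miR-5115 at 4.02 (others 3.18 to 3.38). Dgcr8 mutant replicate 7 at 2 months had miR-467e-5p at 3.38 (others 3.18 to 3.27). Dgcr8 wild-type replicate 3 at 4 months had miR-7a-1-3p at 5.26 (others 5.53 to 5.74). The animals named most often were Df16 mutant replicate 1 at 2 months, apart in both directions, and Dgcr8 mutant replicate 5 at 2 months, lower in each but miR-540-5p, which lay near the floor.

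The miRNAs miR-204-5p and miR-211-5p of the choroid plexus list stood apart in the same animal, Df16 mutant replicate 3 at 4 months. No technical or biological explanation was tested for it.

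The effect of the mutation on miR-185-5p differed between the lines by limma, with Df16 minus Dgcr8 at -1.15 at 2 months and -1.08 at 4 months. A candidate explanation is the loss of 1 gene copy in Df16 on top of the change in Dgcr8 mutants, which would give a difference near -1, and the 95% intervals of -1.32 to -0.99 and -1.25 to -0.90 hold that value at both ages. Over the 16 combinations of scaling, background or authors' values with age the interval held -1 in 10, lay below it in 3 (quantile normalization at 2 months and the authors' values at both ages) and above it in 3 (normexp at both ages, at -0.57 and -0.59, and spike-in scaling at 4 months, at -0.55), so that whether the size is that of 1 lost copy is left open. As for array scaling, the difference lay at -0.549 or lower over the same 16 combinations, with a highest upper 95% bound of -0.132, which argues against it as the whole cause. The criterion was set 4 times, each after the values were seen: a difference below -0.5 without spike-in scaling (met in 14 of 14), upper bounds below -0.5 (met in 14 of 16, missed under normexp) and below 0 for the difference relative to the median of all miRNAs, which a factor per array cannot move, and an upper bound below 0 for the difference itself (met in 16 of 16).

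Arrays of mutants were dimmer than those of wild types before scaling, by -0.23 on the log2 scale as a mean of the 4 comparisons. Within slides that held both genotypes the weighted mean difference was -0.229 (within-slide permutation p = 0.00022, 11 slides, with slides 1 and 2, which held the same animals, taken as 1), which argues against slide as the whole cause. Labelling or hybridisation efficiency stays open: the labelling spike-ins were themselves lower by -0.147 in mutants (permutation p = 0.0333), and the brightness over the spike-ins differed by -0.0794 (permutation p = 0.279), but the first was higher in Dgcr8 at 4 months (0.112) and the second in Df16 at 4 months (0.248). A lower amount of miRNA in mutants, which the loss of a Dgcr8 copy could give, cannot be told apart from labelling with these values.

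The 40 miRNAs lower in both lines at 4 months were refitted in Dgcr8. With array brightness in the model they kept 1.03 (jackknife SE 0.0745) of their median difference, and with slide 1.03 (SE 0.0700). All 40, chosen as lower, stayed so in both fits. These values argue against slide as the whole cause in Dgcr8, but cannot test brightness, already divided out. The mutation, which the design varies, stays open.

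Other splits of the same animals gave as many calls as the real one in 1 of 100 splits for Df16 at 2 months, real split included (101 calls, highest other 77), in 1 of 35 for Df16 at 4 months (50, highest other 22), in 1 of 100 for Dgcr8 at 2 months (111, highest other 85) and in 2 of 100 for Dgcr8 at 4 months (90, highest other 138). For Df16, where the numbers were taken as pairs, the splits that part all 4 pairs are too few for a share under 1 in 20: 16 at 2 months, with 35 calls in the highest other, and 8 at 4 months, with 3 in the highest other. The splits that do not part all pairs gave at most 77 and 22 calls. For Dgcr8 the shares lay under 1 in 20, though splits were not held within slides. At 4 months another split called more miRNAs than genotype did, for a reason not tested. It put 5 mutants and 2 wild types on 1 side, so that genotype enters it in part. For the wild types' ages it was 1 of 100 in Df16 (299, highest other 244) and 1 of 100 in Dgcr8 (150, highest other 91). A count of 1 between the lines was reached in 12 of 100 splits at 2 months (highest other 109) and 22 of 100 at 4 months (highest other 9), so that chance cannot be excluded for the count, which does not test miR-185-5p, the miRNA called. The count of the change with age was 0, which every split matches (100 of 100), so that the splits decide nothing there (highest other 42 in Df16 and 103 in Dgcr8). In these splits genotype itself can enter the contrast, so that their highest counts were not traced to a structure of the animals.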

How the results depend on the processing

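Scaling to the labelling spike-ins and array brightness as a covariate were chosen after the data were seen, and the other alternatives before. Over 204 single-miRNA results with 14230 values under alternatives, animals left out included, 13237 kept direction and side of the threshold, 819 no longer passed, 53 newly passed and 121 turned direction. The calls of miR-185-5p passed in each comparison under every alternative run. The counts of calls lay between 65 and 259 for Df16 at 2 months, 3 and 146 for Df16 at 4 months, 9 and 165 for Dgcr8 at 2 months and 13 and 230 for Dgcr8 at 4 months. In each sentence the value in brackets after a count or correlation is that of the report, and effect by age is the change of the mutant effect with age. Values of miRNAs not well above background in a group show direction only. Where nothing else is said, the cause was not tested.

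With the percentile taken over all probes there were 22 calls in Df16 at 4 months (50), 2 between the lines at 4 months (1), 281 age calls in Dgcr8 wild types (150) and 18 miRNAs lower in both lines at 4 months (40). Here miR-338-3p did not pass in Df16 at 2 months (-0.24, adjusted p = 0.188), in Df16 at 4 months (-0.36, adjusted p = 0.154) and in Dgcr8 at 4 months (-0.27, adjusted p = 0.0788). With quantile normalization there were 4 calls for effect by age in Df16 (0), 1 for effect by age in Dgcr8 (0), 2 between the lines at 4 months (1) and 234 age calls in Dgcr8 wild types (150). Then miR-338-3p passed in Dgcr8 at 2 months (-0.24, adjusted p = 0.00732). miR-338-5p (0.023) was positive in Dgcr8 at 2 months. miR-125b-5p (-0.022) was negative in Df16 at 2 months. With median scaling over miRNAs detected in all animals there were 2 calls between the lines at 2 months (1) and 2 between the lines at 4 months (1). Under this setting miR-338-3p did not pass in Df16 at 2 months (-0.24, adjusted p = 0.0904) and in Df16 at 4 months (-0.34, adjusted p = 0.0674). miR-467e-5p (0.11) was positive in Df16 at 2 months.

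Without scaling there were 173 calls in Df16 at 2 months (101), 14 in Df16 at 4 months (50), and 126 and 14 miRNAs lower in both lines at 2 and 4 months (65 and 40). In this fit miR-338-3p did not pass in Df16 at 4 months (-0.42, adjusted p = 0.103) and miR-338-3p passed in Dgcr8 at 2 months (-0.36, adjusted p = 0.00527). miR-1306-3p (-0.22), miR-697 (-0.0023), miR-30d-5p (-0.046), miR-30a-3p (-0.066), miR-344d-3p (-0.065), miR-30a-5p (-0.095), miR-320-3p (-0.12) and miR-677-3p (-0.13) were negative in Df16 at 2 months. Also negative there were miR-3096b-3p (-0.13), miR-3102-3p (-0.15), miR-1839-3p (-0.17), miR-484 (-0.18), miR-138-1-3p (-0.16), miR-1839-5p (-0.19), miR-125b-5p (-0.23), miR-6366 (-0.15) and miR-26a-5p (-0.24). miR-1306-3p (-0.20), miR-1839-5p (-0.0038), miR-1839-3p (-0.012), miR-320-3p (-0.025), miR-484 (-0.024), miR-138-1-3p (-0.046), miR-3096b-3p (-0.049) and miR-30a-5p (-0.067) were negative in Dgcr8 at 2 months. Also negative there were miR-30a-3p (-0.069), miR-125b-5p (-0.083), let-7b-5p (-0.067), miR-219-2-3p (-0.033), miR-29a-3p (-0.072), let-7c-5p (-0.064) and miR-30c-2-3p (-0.018). miR-484 (-0.0030) and miR-1839-3p (-0.020) were negative in Dgcr8 at 4 months. By construction every difference then carries the difference in brightness between the groups.

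With normexp background correction there were 259 calls in Df16 at 2 months (101), 3 in Df16 at 4 months (50), 9 in Dgcr8 at 2 months (111) and 13 in Dgcr8 at 4 months (90). There were also 42 age calls in Dgcr8 wild types (150), 5 and 3 miRNAs lower in both lines at 2 and 4 months (65 and 40) and 8 list shifts by camera (5). Here miR-338-3p did not pass in Df16 at 4 months (-0.32, adjusted p = 0.0783). The camera call was lost for Dlk1-Dio3 in Df16 at 4 months (median 0.011, adjusted p = 0.352). The correlation of mutant effects was 0.59 for Df16 at 2 months with Dgcr8 at 4 months (0.77), 0.38 for Df16 at 4 months with Dgcr8 at 2 months (0.56), 0.36 for Df16 at 4 months with Dgcr8 at 4 months (0.66) and 0.70 for Dgcr8 at 2 months with Dgcr8 at 4 months (0.85). miR-338-5p (0.24), miR-25-3p (0.081), miR-379-3p (0.16), miR-299b-5p (0.098), miR-337-3p (0.0060), miR-544-5p (0.23), miR-340-3p (0.11) and miR-374c-5p (0.19) were positive in Df16 at 2 months. Also positive there were miR-376c-3p (0.13), miR-325-3p (0.20), miR-337-5p (0.12), miR-369-3p (0.32), miR-539-5p (0.28), miR-873a-5p (0.098), miR-382-3p (0.0046), miR-7a-1-3p (0.13) and miR-467e-5p (0.28). miR-338-5p (0.014), miR-1306-3p (0.011), miR-130b-3p (0.0070), miR-532-3p (0.0028), miR-342-5p (0.020) and miR-212-5p (0.025) were positive in Df16 at 4 months. miR-338-5p (0.17), miR-379-3p (0.055), miR-540-5p (0.15), miR-544-5p (0.12), miR-374c-5p (0.085), miR-299b-5p (0.031), miR-539-5p (0.16) and miR-582-3p (0.13) were positive in Dgcr8 at 2 months. Also positive there were miR-376c-3p (0.021), miR-337-5p (0.021), miR-369-3p (0.047), miR-342-5p (0.15), miR-488-3p (0.046), miR-382-3p (0.0070), miR-467e-5p (0.17) and miR-467b-5p (0.11). miR-338-5p (0.092), miR-379-3p (0.011), miR-374c-5p (0.012), miR-325-3p (0.047), miR-540-5p (0.10), miR-532-3p (0.064), miR-490-3p (0.035) and miR-130b-3p (0.062) were positive in Dgcr8 at 4 months. Also positive there were miR-342-5p (0.10), miR-212-5p (0.057), miR-488-3p (0.0089) and miR-7a-1-3p (0.020). miR-379-3p (0.034) was positive for age in Df16 wild types. miR-505-5p (-0.21) and miR-582-5p (-0.19) were negative for effect by age in Df16. miR-325-5p (-0.065) was negative for effect by age in Dgcr8. By construction the offset of 50 shrinks the differences of dim miRNAs, and what turned their sign was not tested.

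With the scanner software's summary per miRNA there were 4 calls for effect by age in Df16 (0) and 2 between the lines at 4 months (1). Then miR-338-3p did not pass in Df16 at 2 months (-0.22, adjusted p = 0.0778). With the mean of the probes' log2 levels there were 3 calls between the lines at 4 months (1). With the brightest probe of each miRNA there were 2 calls between the lines at 4 months (1). miR-338-5p (0.052) was positive in Dgcr8 at 2 months. On the authors' series values there were 228 age calls in Dgcr8 wild types (150) and 24 miRNAs lower in both lines at 4 months (40). In this fit miR-338-3p did not pass in Df16 at 2 months (-0.19, adjusted p = 0.0661). Lost by camera was the call for Dlk1-Dio3 in Df16 at 4 months (median -0.072, adjusted p = 0.0676). miR-212-5p (0.0080) was positive in Df16 at 4 months. With the floor at 0.5 of its level there were 2 calls for effect by age in Df16 (0). With 4 times the floor there were 67 calls in Dgcr8 at 2 months (111), 58 in Dgcr8 at 4 months (90), 7 for effect by age in Df16 (0) and 6 between the lines at 4 months (1). There were also 80 age calls in Dgcr8 wild types (150) and 39 miRNAs lower in both lines at 2 months (65). miR-338-5p (0.016) was positive in Dgcr8 at 2 months. By construction a higher floor leaves dim miRNAs with no difference. With outlier spots kept the correlation of mutant effects was 0.64 for Df16 at 2 months with Dgcr8 at 2 months (0.79), 0.56 for Df16 at 2 months with Dgcr8 at 4 months (0.77) and 0.73 for Dgcr8 at 2 months with Dgcr8 at 4 months (0.85). With no filter there were 10 list shifts by camera (5). Under this setting miR-338-3p did not pass in Df16 at 2 months (-0.26, adjusted p = 0.0741). Here 1247 miRNAs were tested in place of 470. Over miRNAs detected in all animals there were 65 calls in Df16 at 2 months (101), 198 age calls in Df16 wild types (299), 82 age calls in Dgcr8 wild types (150) and 40 miRNAs lower in both lines at 2 months (65). There were also 3 list shifts by camera (5). The camera call was lost for Dlk1-Dio3 in Df16 at 4 months (median -0.13, adjusted p = 0.111) and choroid plexus in Df16 at 4 months (median 0.77, adjusted p = 0.385). Here 289 were tested, and others had no value.

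When the groups of each comparison were fitted alone there were 13 calls in Df16 at 4 months (50), 3 for effect by age in Df16 (0), 2 between the lines at 4 months (1) and 11 miRNAs lower in both lines at 4 months (40). Here miR-338-3p did not pass in Df16 at 4 months (-0.34, adjusted p = 0.0534). Lost by camera was the call for choroid plexus in Df16 at 4 months (median 0.78, adjusted p = 0.259). The spread was then taken from fewer animals. With array weights there were 156 calls in Df16 at 2 months (101), 146 in Df16 at 4 months (50), 230 in Dgcr8 at 4 months (90) and 63 for effect by age in Df16 (0). There were also 32 calls for effect by age in Dgcr8 (0), 67 between the lines at 4 months (1), 69 miRNAs lower in both lines at 4 months (40) and 3 list shifts by camera (5). The camera call was lost for Dlk1-Dio3 in Df16 at 4 months (median -0.031, adjusted p = 0.244) and choroid plexus in Df16 at 4 months (median 0.058, adjusted p = 0.677). The correlation of mutant effects was 0.74 for Dgcr8 at 2 months with Dgcr8 at 4 months (0.85). miR-338-5p (0.038) was positive in Dgcr8 at 2 months. miR-1306-3p (-0.0070) was negative in Df16 at 2 months. The estimation of the weights did not converge. Under slide as a fixed block there were 177 calls in Dgcr8 at 4 months (90), 2 for effect by age in Df16 (0) and 5 between the lines at 4 months (1). Lost by camera was the call for choroid plexus in Df16 at 4 months (median 0.78, adjusted p = 0.0762). miR-338-5p (0.017) was positive in Dgcr8 at 2 months. Under slide as a random block there were 2 calls for effect by age in Df16 (0) and 5 between the lines at 4 months (1). At an adjusted p under 0.1 there were 3 calls between the lines at 4 months (1). At an unadjusted p under 0.05 there were 88 calls in Df16 at 4 months (50), 38 for effect by age in Df16 (0), 19 for effect by age in Dgcr8 (0) and 18 between the lines at 2 months (1). There were also 17 calls between the lines at 4 months (1).

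With the replicate block miR-338-5p (0.042) was positive in Dgcr8 at 2 months. Replicate numbers in the Dgcr8 groups mark no known pair: same-numbered animals correlated with r from -0.38 to 0.57 at 2 months, 2 of 7 best with their own number, and from -0.28 to 0.45 at 4 months, 1 of 7 best with their own. With the block miR-5113, miR-3095-3p and miR-219-2-3p did not pass in Dgcr8 at 2 months. In Df16, where the numbers were taken as pairs, the block gave 92 calls at 2 months (74 and 18) and 70 at 4 months (57 and 13), and miR-6366 did not pass at 2 months (0.25, adjusted p = 0.157). For the results named in the text, beside these and those given with the block in the report, the replicate block changed no other call.

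With scaling to the labelling spike-ins there were 7 calls in Df16 at 4 months (50), 158 in Dgcr8 at 4 months (90), 148 between the lines at 4 months (1) and 1 miRNA lower in both lines at 4 months (40). There were also 3 list shifts by camera (5). Then miR-338-3p did not pass in Df16 at 2 months (-0.41, adjusted p = 0.0836) and in Df16 at 4 months (-0.096, adjusted p = 0.802). The camera call was lost for Dlk1-Dio3 in Df16 at 4 months (median 0.11, adjusted p = 0.0990) and choroid plexus in Df16 at 4 months (median 1.03, adjusted p = 0.0786). miR-1306-3p (0.19) and miR-30e-5p (0.063) were positive in Df16 at 4 months. miR-1306-3p (-0.063) was negative in Dgcr8 at 2 months. miR-1306-3p (-0.065), miR-1843a-5p (-0.083), miR-3102-3p (-0.086), miR-3096b-3p (-0.10), miR-1839-5p (-0.10), miR-484 (-0.12) and miR-1839-3p (-0.13) were negative in Dgcr8 at 4 months. By construction the median of all miRNAs then shifted, by -0.08 and 0.24 in Df16 and -0.06 and -0.23 in Dgcr8 at 2 and 4 months. With array brightness as a covariate miR-338-5p (0.0091) was positive in Dgcr8 at 2 months. miR-1306-3p (-0.038) was negative in Dgcr8 at 2 months. miR-6366 (-0.0073) was negative in Df16 at 2 months.

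With 1 animal left out at a time, miR-338-3p lay between -0.33 and -0.19 in Df16 at 2 months and between -0.39 and -0.30 at 4 months. The Dlk1-Dio3 median in Df16 at 4 months lay between -0.15 and -0.019, the choroid plexus median between 0.0082 and 1.04, and list shifts numbered 3 to 5. Calls between the lines at 4 months numbered 1 to 4, and calls for effect by age 0 to 1 in each line. The difference of miR-1306-3p lay between -0.23 and 0.12 in Df16 at 4 months and between -0.039 and 0.23 in Dgcr8 at 2 months, and that of miR-338-5p between -0.084 and 0.065 in Dgcr8 at 2 months.

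Signal over background limits the dim miRNAs: 29.2 to 43.6% of spots on an array were negative after background subtraction, and 3 tested miRNAs lay at the floor in every animal.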

Other observations

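Both tests in this part, on the arms of precursors and on miR-6366, were chosen after the values were seen.

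The 5p and 3p arms of a precursor are made from 1 transcript and may change together. Over the 58 precursors outside the Dlk1-Dio3 list with both arms tested, the differences of the arms correlated with a mean r of 0.700 over the 4 comparisons (1-sided re-pairing permutation p = 1e-05, the smallest that 100000 resamples can give). Arms are not independent replicates, and array effects common to both arms are not excluded by this test.

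The gene annotated as Mir6366 lies in the deleted interval between Dgcr6 and Dgcr8, and the 2 probes named miR-6366 were the brightest miRNA on the array (mean log2 level 18.1). Its difference was 0.25 in Df16 at 2 months (adjusted p = 0.0440 by limma), and the call was lost with the replicate block (adjusted p = 0.157) and with 1 animal left out in 5 runs (0.16 without mutant replicate 1), and kept by 9 of 22 alternatives. Without scaling it was -0.15, with array brightness as a covariate -0.0073. A level following gene copies would lie near -1 in Df16 against Dgcr8, but the lowest 95% bound over both ages was -0.31. Lower bounds of miR-1306-3p, also deleted, were -0.31 and -0.58 in Df16 at 2 and 4 months, so what miR-6366 probes measure stays open.

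Arrays of 1 animal, where 2 were made, correlated with r from 0.995 to 0.999, and their differences had an SD of 0.13 to 0.27 against 0.15 to 0.61 between pairs of animals of 1 group.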
